A study of Homo sapiens with 12 samples.

How the data were processed

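Polyadenylated RNA from 12 samples of the human cell line K562 was sequenced. The samples were wildtype cells and the bortezomib-resistant lines BR1 and BR2, each untreated or treated with geldanamycin, with 2 samples in each of 6 groups. RNA was isolated with Trizol and libraries were made with a directional NEBNext Ultra II kit, per the labels' protocols. Reads were aligned to GRCh38 and compared with DESeq2, per the submitters' processing notes, which state no versions. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands may share reads. All samples carry the same batch label, so no comparison was confounded with a batch the labels give.

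The authors deposited 4 tables of 62130 genes with gene identifiers, symbols, raw counts per sample and the results of a comparison. Whole-number counts per gene were deposited for each sample with no normalization, per the file headers and the values. Each sample title covers technical replicates 1 and 2, while the tables hold 1 count column per sample. How the technical replicates were joined is not stated, so each column was taken as 1 sample. The deposited log2 fold changes are the authors' DESeq2 estimates for resistant against wildtype cells and for treated against untreated cells in each line, per the file headers. The authors' adjusted p-values stand beside them, per the file headers, with the adjustment method not stated. These deposited values were used only as an alternative.

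Counts were joined by gene identifier and sample column, and 20966 identifiers without a symbol were kept in the tests. Gene positions, biotypes, the length of the principal transcript and GC content came from GENCODE 29 on GRCh38, which may not be the release used for counting. Symbols in the text are those in the deposited tables. Total counts per sample ranged from 10347281 to 22799884, the 10 most abundant genes held 6.34% to 7.50% of counts, and mitochondrially encoded genes held 2.44% to 6.05%.

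Genes were filtered with edgeR 4.0.16 (filterByExpr), which kept 18490 genes and at least 99.8% of the counts of each sample. Counts were scaled with TMM factors, and edgeR's quasi-likelihood test was fitted with 1 mean per group over all 12 samples, which left 6 residual degrees of freedom. Comparisons were the mean of BR1 and BR2 against wildtype cells, each line against wildtype cells, BR2 against BR1, treated against untreated cells in each line, and the difference of the geldanamycin responses between lines. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values use the TMM-scaled library sizes. A fold against a group with no counts was computed against 3 counts over the whole group and is a lower bound, and with 1 to 3 counts a ratio of counts is given with its exact 95% binomial interval. For BR1 and BR2 together against wildtype cells, the counts of both lines were summed before such a fold or ratio was taken. The overlap of the 3 responses was set against the number expected of independent lists. For the comparisons that share the wildtype libraries, 20 data sets with no change between groups were simulated.

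There were 571 genes on 32 lists, of which 30 had at least 3 genes past the filter and were tested. They covered the heat shock response, the TRiC chaperonin, proteasome subunits, the immunoproteasome and proteasome activators, the unfolded protein response of the endoplasmic reticulum and the ATF4 integrated stress response. They also covered the NRF2 response, autophagy and ubiquitin receptors, ABC drug transporters, the BCL2 family, STAT5 and MAPK targets, G2/M genes, DNA replication, growth arrest, erythroid and megakaryocyte genes. Further lists were cholesterol synthesis, glycolysis and hypoxia, cytosolic ribosomal proteins, mitochondrially encoded transcripts, nuclear oxidative phosphorylation, the interferon response, NF-kappaB targets, metallothioneins, immediate early genes, and markers of T lymphocytes, B lymphocytes and plasma cells, monocytes, granulocytes, epithelial, mesenchymal and endothelial cells. SLC7A11 was on 2 lists. Each list was tested with camera in limma 3.58.1 on voom values with the preset correlation of 0.01 and, as an alternative, with a correlation estimated from the residuals, and p-values were adjusted over the lists of a comparison. Fold changes of a list's genes were also adjusted over the list alone. In lists whose median, mean and test differed in sign, the adjusted p of camera was above 0.05 in every comparison.

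Named genes were the 8 largest rises and the 8 largest falls of each comparison among protein-coding symbols past the threshold. They had at least 10 CPM in the higher group and no overlap between the samples of the groups compared. The absence of overlap was not required for differences of responses. The 3 members of each described list with the smallest p-values were named as well, and 17 genes were followed in every comparison (PSMB5, ABCB1, HSPA1A, HSPA1B, DNAJB1, HSP90AA1, HSP90AB1, HSF1, HMOX1, NFE2L1, SQSTM1, MCL1, BCL2L1, ABL1, BCR, GATA1 and HBG1). Some of the genes this rule names are not reported here. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Near-identical copies such as HSPA1A and HSPA1B, HBG1 and HBG2, the metallothioneins and ribosomal protein genes with their pseudogenes are uncertain, since the counting may split or drop their reads.

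Alternatives were DESeq2 size factors (RLE) in place of TMM, no count filter, a stricter filter of 5 CPM, a fit on only the groups compared, the sample number as a replicate block, DESeq2 1.42.0 in place of edgeR, stricter thresholds, the authors' deposited values, both lines pooled as 1 group, camera with an estimated correlation, fry, and leaving out each sample in turn. Removal of each library's trend with transcript length and GC content by splines with 4 degrees of freedom, and a block with crossed sample numbers, were added after seeing the data. The removal was incomplete where the trend was strong. Spearman's rho of log2 fold change with length was then still -0.147 for geldanamycin in BR1. It was -0.13 for the difference between the BR1 and wildtype responses. The length of the principal transcript replaced the summed length of all exons after the values were seen. Length and GC content were known for 95.5% of the genes tested. The steps were tested on simulated data before use, and all ran in R 4.3.3. The deviations of equally numbered treated and untreated samples from their group means correlated at -0.403 in wildtype cells, 0.191 in BR1 and 0.0206 in BR2. The differences between the samples of a group also followed GC content. Their rho was -0.531 untreated and 0.439 treated in wildtype cells, -0.417 and -0.55 in BR1, and 0.316 and 0.104 in BR2. Whether the sample numbers pair treated with untreated samples therefore cannot be told from these correlations.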

Results

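Polyadenylated RNA was sequenced from K562 cells, an established chronic myeloid leukaemia line that carries the BCR-ABL1 fusion and has erythroid features. The samples came from the wildtype line and from 2 bortezomib-resistant K562 lines, BR1 and BR2, each untreated and treated with geldanamycin. Bortezomib inhibits the proteasome, mainly through its PSMB5 subunit, and geldanamycin inhibits the chaperone HSP90. The dose and duration of geldanamycin are not given in the sources used here. The 12 samples formed 6 groups of 2. Total counts per sample were 16412306 and 15819551 in untreated wildtype cells, 19959827 and 19579214 in BR1, and 20133165 and 17815786 in BR2. With geldanamycin they were 10347281 and 18908176 in wildtype cells, 22799884 and 20000012 in BR1, and 15416513 and 13338640 in BR2. Levels are counts scaled to the library size (CPM) as mean ± SD with n = 2 in every group, and log2 fold changes carry their standard error (SE). The first principal component held 45.9% of the variance and separated resistant from wildtype libraries. The second held 21.2% and separated treated from untreated libraries, and the third held 12.3% and separated BR1 from BR2. The series design text calls the duplicates biological but does not say what separated them. P-values of single genes therefore measure the spread between these samples only. Those of camera set a list's genes against the other genes and depend on the correlation assumed between genes. Floors and counting intervals cover counting error only.

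The comparison of the untreated resistant lines with untreated wildtype cells addressed what distinguished the 2 bortezomib-resistant lines. The sample titles do not say how these lines were derived. Resistance therefore cannot be told apart from other differences between these lines and the wildtype line. The p-values do not cover variation between lines. PAX3, a transcription factor of neural crest and muscle development (ENSG00000135903, GRCh38 chromosome 2, 222199887 to 222298998), had no counts in wildtype cells. It stood at 19.3 ± 1.04 CPM in BR1 and 25.9 ± 0.875 CPM in BR2 and was at least 241-fold higher in the resistant lines. The small heat shock protein gene HSPB8 (ENSG00000152137, chromosome 12, 119171555 to 119224855) also had no counts in wildtype cells. It stood at 12.9 ± 1.41 CPM in BR1 and 15.3 ± 0.116 CPM in BR2 and was at least 151-fold higher. FN1, which encodes the matrix protein fibronectin (ENSG00000115414, chromosome 2, 215360440 to 215436073), fell from 2126 ± 573 CPM to 7.49 ± 1.14 CPM in BR1 and 3.23 ± 0.00834 CPM in BR2. Its log2 fold change was -8.76 ± 0.15 (adjusted p = 1.53e-22). IL2RA, the alpha chain of the interleukin 2 receptor, fell from 60.4 ± 4.07 CPM to 0.0256 ± 0.0362 CPM in BR1 and 0.054 ± 0.00523 CPM in BR2. The ratio was 1550 with a 95% counting interval of 529 to 7510. Among the other genes with the largest rises, TNFRSF19 was at least 114-fold higher and the chloride channel gene ANO1 was 376 times higher (interval 129 to 1820). ADGRG6 was 226 times higher (62.3 to 1870) and TNS3 was 162 times higher (55.2 to 785). Such folds and ratios pool the counts of both resistant lines and can hide a difference between them. In BR1 alone ADGRG6 was 425 times higher (117 to 3510), while it was not among the 8 largest rises in BR2. DOCK5 and PODXL rose by log2 fold changes of 6.52 ± 0.36 and 5.95 ± 0.21. Among the other largest falls, PRR16 was at least 307-fold lower, ST8SIA4, a polysialyltransferase gene, was 1540 times lower (425 to 12700), and TRDN was 657 times lower (181 to 5440). PTPRR was 645 times lower (178 to 5340), ANK3 was 507 times lower (173 to 2470) and PRKCH, a protein kinase C gene, was 501 times lower (171 to 2440).

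Proteasome subunit genes were higher in the resistant lines. Of 33 tested, 26 rose, 0 fell and 7 did not pass, with a median log2 fold change of 0.54. When adjusted over the list alone, 27 rose and 0 fell. The list passed camera's test (adjusted p = 5.61e-13), and this call was lost with adjusted p = 0.163 with an estimated correlation. PSMB2 rose from 178 ± 7.34 CPM to 326 ± 13.5 CPM in BR1 and 384 ± 11.1 CPM in BR2, a log2 fold change of 0.99 ± 0.09. The base subunit gene PSMC2 rose by 0.89 ± 0.10. PSMB5, the subunit that bortezomib binds (ENSG00000100804, chromosome 14, 23016543 to 23035230), rose from 168 ± 4.27 CPM to 207 ± 1.83 CPM in BR1 and 247 ± 12.3 CPM in BR2. Its log2 fold change was 0.42 ± 0.09 (adjusted p = 0.000788). Of 6 immunoproteasome and proteasome activator genes, 4 rose and 0 fell, over all genes and when adjusted over the list alone. The median was 0.40, and PSMB10 (0.89 ± 0.12) and PSME2 (0.85 ± 0.10) were among them. PSMB10 rose by 1.26 ± 0.13 in BR2 and by 0.53 ± 0.14 in BR1, and was higher in BR2 than in BR1 (0.73 ± 0.13, adjusted p = 0.000332). That list passed with adjusted p = 0.0239, and had adjusted p = 0.174 with an estimated correlation. It had adjusted p = 0.055 with a median of 0.33 once each library's trend with transcript length and GC content was removed.

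Erythroid genes were also higher in the resistant lines. Of 24 tested, 18 rose, 2 fell and 4 did not pass, with a median of 0.81 (adjusted p = 1.26e-07, and adjusted p = 0.031 with an estimated correlation). When adjusted over the list alone, 18 rose and 3 fell. HBZ, the embryonic zeta globin gene, rose from 134 ± 22.3 CPM to 598 ± 66.4 CPM in BR1 and 699 ± 44.8 CPM in BR2, and HEMGN rose by 2.10 ± 0.13. HEMGN encodes hemogen, a nuclear protein of blood progenitors. The fetal globin gene HBG1 rose by 0.71 ± 0.12, although reads of HBG1 and HBG2 are hard to tell apart. Of 6 megakaryocyte genes past the count filter, 1 rose and 3 fell, also when adjusted over the list alone, and the list did not pass (median -0.87, adjusted p = 0.547).

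The lists of the ATF4 response and the unfolded protein response were lower in the untreated resistant lines. Of 23 genes of the ATF4 integrated stress response, 2 rose, 16 fell and 5 did not pass, with a median of -0.60 (adjusted p = 1.71e-06, and adjusted p = 0.0356 with an estimated correlation). Over the list alone, 3 rose and 16 fell. CHAC1, a glutathione-degrading enzyme gene (ENSG00000128965, chromosome 15, 40952962 to 40956512), fell from 21.6 ± 1.37 CPM to 4.03 ± 0.538 CPM in BR1 and 2.73 ± 0.302 CPM in BR2. DDIT4, an inhibitor of mTORC1 signalling, fell by 1.21 ± 0.09. Of 21 genes of the unfolded protein response of the endoplasmic reticulum, 0 rose and 14 fell, also when adjusted over the list alone. ERN1 stood at -1.12 ± 0.11 and HERPUD1 at -0.65 ± 0.09. ERN1 lies in a region of chromosome 17, described under other observations, whose genes were lower as a group in both lines. The list's median was -0.37 (adjusted p = 6.19e-05), lost with adjusted p = 0.226 with an estimated correlation. Of 32 heat shock response genes, 6 rose and 7 fell, also when adjusted over the list alone. The list did not pass (median 0.04, mean -0.02, adjusted p = 0.785). The inducible HSP70 genes HSPA1A and HSPA1B, whose reads are hard to tell apart, were lower, at -0.35 ± 0.09 and -0.61 ± 0.10. Their cochaperone gene DNAJB1 fell by 0.59 ± 0.09. HSP90AA1 (-0.07 ± 0.10, adjusted p = 0.623) and HSP90AB1 (0.00 ± 0.11, adjusted p = 0.997) did not pass. Of 8 TRiC chaperonin genes, 0 rose and 1 fell, also over the list alone (median 0.18, adjusted p = 0.476).

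Immediate early genes were lower in the resistant lines as well. Of 14 tested, 1 rose and 10 fell, also when adjusted over the list alone, with a median of -0.67 (adjusted p = 4.97e-05, lost with adjusted p = 0.241 with an estimated correlation). EGR1 fell from 256 ± 3.96 CPM to 79.3 ± 2.03 CPM in BR1 and 91.4 ± 3 CPM in BR2. Of 22 cholesterol synthesis genes, 0 rose and 12 fell, and 13 fell when adjusted over the list alone (median -0.28, adjusted p = 0.00131, lost with adjusted p = 0.235 with an estimated correlation). Of 6 metallothionein genes, which share near-identical sequence, 3 rose and 0 fell, also over the list alone. Their median was 2.35 (adjusted p = 0.0213, lost with adjusted p = 0.174 with an estimated correlation and lost when both lines were pooled as 1 group). MT2A rose from 4.41 ± 0.87 CPM to 40.6 ± 0.73 CPM in BR1 and 16.3 ± 2.76 CPM in BR2. MCL1, an antiapoptotic BCL2 family gene, fell from 511 ± 20.9 CPM to 281 ± 13 CPM in BR1 and 247 ± 3.45 CPM in BR2. NFE2L1, the transcription factor that induces proteasome genes, fell by 0.70 ± 0.11. It lies in a region of chromosome 17, described under other observations, whose genes were lower as a group in both lines. BCL2L1 (-0.07 ± 0.09, adjusted p = 0.596), SQSTM1 (-0.15 ± 0.10, adjusted p = 0.282), BCR (0.18 ± 0.16, adjusted p = 0.421) and GATA1 (-0.15 ± 0.09, adjusted p = 0.187) did not pass. ABCB1, the drug efflux pump gene, was below the count filter. It had 2 counts in wildtype cells, 2 in BR1, 5 in BR2, and 5, 9 and 11 in the corresponding treated groups.

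Further lists gave smaller or less stable differences between the resistant lines and wildtype cells. Of 22 DNA replication genes, 10 rose and 2 fell (11 and 2 over the list alone, median 0.24, adjusted p = 0.0166). Of 40 nuclear oxidative phosphorylation genes, 10 rose and 1 fell, also over the list alone (median 0.20, adjusted p = 0.0052). These calls were lost with adjusted p = 0.368 and adjusted p = 0.439 with an estimated correlation. Of 25 G2/M genes, 1 rose and 9 fell, also over the list alone (median -0.19, adjusted p = 0.0331). Of 21 STAT5 and MAPK targets, 3 rose and 11 fell (3 and 13 over the list alone, median -0.31, adjusted p = 0.0272). SPRY4, a feedback inhibitor of MAPK signalling, stood at -2.02 ± 0.11. Of 29 glycolysis and hypoxia genes, 4 rose and 11 fell (4 and 14 over the list alone, median -0.22, adjusted p = 0.0341). These 3 lists had adjusted p = 0.368 with an estimated correlation. Of 53 cytosolic ribosomal protein genes, 5 rose and 2 fell, and 0 passed over the list alone (median 0.14, adjusted p = 0.0223, and adjusted p = 0.713 with an estimated correlation). The G2/M list did not pass without wildtype sample 1 (median -0.24) or 2 (-0.19), and the STAT5 and MAPK list without wildtype sample 2 (-0.32). Calls were also lost for the glycolysis list without wildtype sample 1 (-0.24), and the ribosomal protein list without wildtype sample 2 (0.08) or BR2 sample 2 (0.12). Neither of these lists passed with each library's trends with transcript length and GC content removed (-0.22 and 0.07), and the glycolysis list did not pass with the stricter count filter. NRF2 targets did not pass (3 of 18 rose, 8 fell, median -0.13, adjusted p = 0.0799). Nor did autophagy and ubiquitin receptors (4 of 18 rose, 5 fell, 5 and 6 over the list alone, median -0.03, adjusted p = 0.62) or ABC drug transporters (3 of 9 rose, 1 fell, median 0.26, adjusted p = 0.134). The BCL2 family did not pass (3 of 19 rose, 7 fell, 3 and 8 over the list alone, median -0.12, adjusted p = 0.321). The same held for growth arrest genes (3 of 10 rose, 2 fell, 3 and 3 over the list alone, median -0.04, mean 0.23, adjusted p = 0.949) and mitochondrially encoded transcripts (0 of 13 passed, median -0.20, adjusted p = 0.321). Interferon genes (3 of 14 rose, 2 fell, median -0.12, adjusted p = 0.848) and NF-kappaB targets (1 of 11 rose, 4 fell, 1 and 5 over the list alone, median -0.20, adjusted p = 0.0867) did not pass either. Where no count over the list alone is given here, it equalled the count over all genes.

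Markers of other cell types were compared between the resistant lines and wildtype cells as well. Of 4 granulocyte markers, 4 fell, also over the list alone (median -1.82, adjusted p = 0.00131, and adjusted p = 0.174 with an estimated correlation). CSF3R, the receptor for granulocyte colony-stimulating factor, fell from 65.3 ± 12.9 CPM to 14.7 ± 1.09 CPM in BR1 and 17.5 ± 0.128 CPM in BR2. Of 5 monocyte markers, 3 fell (4 over the list alone), with ITGAM at -3.36 ± 0.15 (median -2.02, adjusted p = 0.0188, and adjusted p = 0.235 with an estimated correlation). This list did not pass without wildtype sample 2 (median -1.48). Of 6 B lymphocyte and plasma cell markers, 3 fell (4 over the list alone), with CD79B at -4.64 ± 0.48 (median -1.03, adjusted p = 0.00886, and adjusted p = 0.163 with an estimated correlation). Of 4 T lymphocyte markers 1 fell (median -0.61, adjusted p = 0.122), and of 4 epithelial markers 2 fell (3 over the list alone, median -0.30, adjusted p = 0.125), with KRT19 at 275 ± 11.3 CPM in wildtype cells. The mesenchymal and endothelial lists had too few genes past the filter to be tested. Their most abundant genes were COL1A1, with 356 counts in wildtype cells, 206 in BR1 and 787 in BR2, and PECAM1, with 161, 17 and 30 counts. The corresponding treated groups had 365, 188 and 1071 counts of COL1A1 and 102, 11 and 16 of PECAM1.

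In all, 6673 of 18490 genes tested differed between the resistant lines and wildtype cells at adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 3199 were higher and 3474 lower, and 2592 differed by at least 2-fold. The calls for HSF1 (-0.27 ± 0.10, adjusted p = 0.0343), ABL1 (-0.33 ± 0.10, adjusted p = 0.0158) and HMOX1 (-1.23 ± 0.36, adjusted p = 0.00875) were not stable. HSF1 did not pass without wildtype sample 1 (-0.26) or 2 (-0.27), BR1 sample 1 (-0.27) or 2 (-0.28), or BR2 sample 1 (-0.23). ABL1 did not pass without wildtype sample 1 (-0.27) or BR2 sample 2 (-0.31), and HMOX1 without wildtype sample 2 (-0.99). None of the 3 passed when both lines were pooled as 1 group, and HSF1 did not pass with length and GC trends removed (-0.18).

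**Figure D1:**
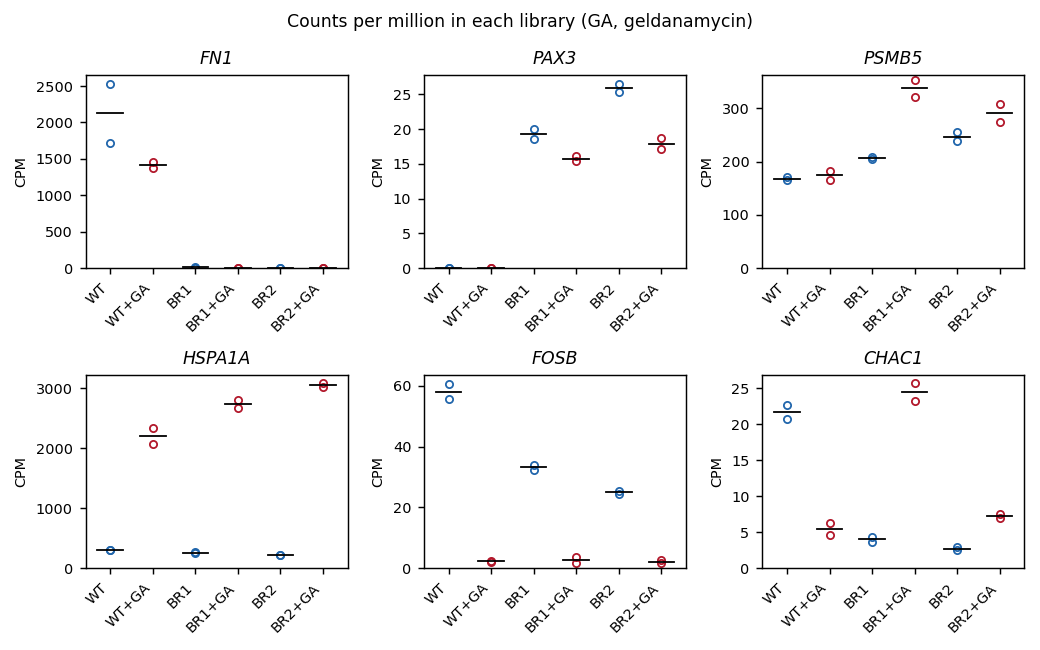
CPM (linear axis from 0) of FN1, PAX3, PSMB5, HSPA1A, FOSB and CHAC1 in wildtype, BR1 and BR2 cells, untreated in blue and geldanamycin-treated in red, where each circle is 1 library and each line the mean of 2. FN1 stands at a mean of 2126 CPM in untreated wildtype cells and 7.49 and 3.23 CPM in untreated BR1 and BR2, and HSPA1A at 2205, 2736 and 3051 CPM in treated wildtype, BR1 and BR2 cells.

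Each resistant line was also compared with wildtype cells by itself. BR1 differed at 6204 genes, 3016 higher and 3188 lower, and BR2 at 5797 genes, 2815 higher and 2982 lower. PAX3 was at least 207-fold higher in BR1 and at least 278-fold higher in BR2, and FN1 had log2 fold changes of -8.15 ± 0.20 and -9.36 ± 0.22. Proteasome subunit genes rose in both lines, with 0 falling in either. In BR1 23 of 33 rose (24 over the list alone, median 0.45, adjusted p = 8.23e-10), and in BR2 26 of 33 rose (27 over the list alone, median 0.60, adjusted p = 2.1e-14). These 2 calls were lost with adjusted p = 0.164 and adjusted p = 0.137 with an estimated correlation. PSMB5 rose by 0.55 ± 0.11 in BR2 (adjusted p = 0.000247) and by 0.30 ± 0.11 in BR1 (adjusted p = 0.0316). The BR1 call for PSMB5 did not pass without wildtype sample 1 (0.27) or 2 (0.32) or BR1 sample 1 (0.29) or 2 (0.29), nor with no count filter. Genes called in both lines in the same direction numbered 1945 higher and 2231 lower, against 459.2 and 514.1 expected of independent lists. A further 35 were higher in BR1 and lower in BR2 and 23 the reverse. Both comparisons share the wildtype libraries, which alone gave a correlation of log2 fold changes across genes of 0.509 in 20 simulations with no change, against 0.894 observed. The covariance was 0.00964 in those simulations (at most 0.0115), against 0.341 observed. The simulations gave 0 shared calls, but with no change in any group hardly any call could arise. That 0 therefore does not show how many of the observed shared calls came from the shared libraries. Genes are not independent replicates in such correlations.

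The resistant lines differed from each other at 1649 genes, 791 higher and 858 lower in BR2 than in BR1. CAMK1D, a calcium-dependent kinase gene (ENSG00000183049, chromosome 10, 12349547 to 12835545), stood at 43.6 ± 0.0677 CPM in BR1, 0.328 ± 0.108 CPM in BR2 and 0.124 ± 0.00277 CPM in wildtype cells. The neighbouring gene CCDC3 (chromosome 10, 12896625 to 13099652) stood at 36.7 ± 2.05 CPM in BR1 and 0.054 ± 0.00523 CPM in BR2, a ratio of 683 (95% counting interval 189 to 5650). MBNL3 (-6.80 ± 0.45), CALN1 (-6.75 ± 0.36), TOX2 (-6.71 ± 0.47), ENAH (-6.48 ± 0.31), the protease gene CTSE (-6.47 ± 0.28) and the growth factor gene BMP7 (-5.89 ± 0.40) were also lower in BR2. PLS3, an actin-bundling protein gene, stood at 34.2 ± 0.348 CPM in BR2, 0.76 ± 0.228 CPM in BR1 and 0.124 ± 0.00277 CPM in wildtype cells. PAGE2B (3.28 ± 0.17), DAB2 (2.66 ± 0.15), the inflammatory caspase gene CASP4 (2.42 ± 0.19) and COL1A1 (2.02 ± 0.19) were higher in BR2. CCR10 (2.36 ± 0.21), FAIM2 (2.21 ± 0.20) and PLPP4 (2.21 ± 0.20) completed the largest rises. Of 22 cholesterol synthesis genes, 4 were higher and 0 lower in BR2 (7 and 0 over the list alone, median 0.18, adjusted p = 0.000262, lost with adjusted p = 0.453 with an estimated correlation). Of 6 metallothionein genes, 0 were higher and 3 lower, also over the list alone (median -1.27, adjusted p = 0.00309, lost with adjusted p = 0.333 with an estimated correlation), MT2A by -1.32 ± 0.15. Ribosomal protein (median 0.15, adjusted p = 0.000262), oxidative phosphorylation (0.18, adjusted p = 0.000648), proteasome (0.11, adjusted p = 0.0272) and TRiC genes (-0.15, adjusted p = 0.0449) also passed as lists, with 1 ribosomal protein and 1 oxidative phosphorylation gene higher, 0 TRiC genes past the test and 1 proteasome gene lower. All 4 lists had adjusted p = 0.84 with an estimated correlation. That proteasome gene, PSMD11, was lower in BR2 (-0.38 ± 0.10), against the direction of its list, and did not pass without BR1 sample 1 (-0.37) or 2 (-0.39) or BR2 sample 1 (-0.37) or 2 (-0.39). Log2 fold changes between the lines fell with transcript length (Spearman's rho = -0.392 across 8292 genes), and 1539 of the 1649 genes were called in the same direction with length and GC trends removed. The first 3 of those lists did not pass without BR2 sample 2 (medians 0.09, 0.17 and 0.06) or with length and GC trends removed (0.06, 0.12 and 0.05). The TRiC list did not pass without BR1 sample 1 (-0.15) or 2 (-0.14), without BR2 sample 2 (-0.15) or with the stricter count filter. The gene count was 848 without BR1 sample 1, 846 without BR1 sample 2, 887 without BR2 sample 1 and 748 without BR2 sample 2, and it was 4636 when fitted on the 2 groups alone.

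The comparison of treated with untreated wildtype cells addressed the response to HSP90 inhibition in cells that were not resistant. HSPA1A (ENSG00000204389, chromosome 6, 31815543 to 31817946) rose from 307 ± 1.77 CPM to 2205 ± 197 CPM, a log2 fold change of 2.85 ± 0.12 (adjusted p = 6.1e-14). CREB3L3, a membrane-bound transcription factor gene (ENSG00000060566, chromosome 19, 4153631 to 4173054), rose from 1.46 ± 0.716 CPM to 36.7 ± 3.45 CPM. SOCS1, an inhibitor of cytokine signalling, rose from 18.3 ± 0.253 CPM to 127 ± 1.15 CPM. FOSB, an immediate early transcription factor gene (ENSG00000125740, chromosome 19, 45467995 to 45475179), fell from 58.1 ± 3.62 CPM to 2.33 ± 0.16 CPM, a log2 fold change of -4.65 ± 0.21 (adjusted p = 3.27e-13). Further rises were C5AR1 (2.68 ± 0.32), QRICH2 (2.60 ± 0.20), the HSP110 gene HSPH1 (2.35 ± 0.12), HSPA1B (2.33 ± 0.12) and SAMD11 (2.12 ± 0.21). Further falls were NR4A1 (-3.56 ± 0.23), MAFF (-2.92 ± 0.17), ATF3 (-2.81 ± 0.14), ADM2 (-2.58 ± 0.23), the proapoptotic gene BBC3 (-2.54 ± 0.14), PPFIA4 (-2.49 ± 0.16) and AREG (-2.35 ± 0.30). HSP90AA1, the inducible HSP90 gene, rose from 1162 ± 97.3 CPM to 2724 ± 150 CPM, and DNAJB1 rose by 1.41 ± 0.11 and SQSTM1 by 0.79 ± 0.12. MCL1 fell by 0.73 ± 0.10, and PSMB5 did not pass (0.05 ± 0.11, adjusted p = 0.755).

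Of 32 heat shock response genes, 27 rose and 1 fell in treated wildtype cells, also when adjusted over the list alone, with a median of 0.91 (adjusted p = 5.13e-21). Of 29 glycolysis and hypoxia genes, 0 rose and 24 fell (25 over the list alone, median -0.87, adjusted p = 1.14e-17). The glucose transporter gene SLC2A3 stood at -1.59 ± 0.12 and the hypoxia-induced genes P4HA1 and NDRG1 at -1.61 ± 0.11 and -2.22 ± 0.18. Of 23 ATF4 response genes, 1 rose and 17 fell (2 and 18 over the list alone, median -0.74, adjusted p = 3.49e-10). The cystine transporter gene SLC7A11 stood at -2.20 ± 0.16 and MTHFD2 at -1.57 ± 0.11. Of 10 growth arrest genes, 0 rose and 6 fell, also over the list alone (median -0.87, adjusted p = 0.000213), with GADD45B at -1.56 ± 0.15. These 4 calls held with adjusted p = 0.0295, 0.0295, 0.0203 and 0.0374 with an estimated correlation. Of 14 immediate early genes, 0 rose and 13 fell, also over the list alone (median -1.5, adjusted p = 2.24e-15, and adjusted p = 0.0606 with an estimated correlation). Of 25 G2/M genes, 0 rose and 13 fell (14 over the list alone, median -0.34, adjusted p = 0.00508, and adjusted p = 0.447 with an estimated correlation). The spindle checkpoint kinase gene BUB1 stood at -0.81 ± 0.12. Proteasome genes (4 of 33 rose, 2 fell, 3 and 1 over the list alone, median 0.12, adjusted p = 0.00465) and TRiC genes (4 of 8 rose, 0 fell, median 0.22, adjusted p = 0.0316) also passed. Both were lost with adjusted p = 0.522 and adjusted p = 0.556 with an estimated correlation. The proteasome list did not pass without treated wildtype sample 2 (median 0.12), and the TRiC list without wildtype sample 1 (0.18) or treated wildtype sample 2 (0.17) or with the stricter count filter. In all, 5856 genes changed, 2656 higher and 3200 lower, and 1580 by at least 2-fold. In data simulated from these libraries, the test recovered 95% of genes changed 2-fold and 68% of genes changed 1.5-fold. Of its calls, 5.82% were false. In those data few genes changed, none of them of low expression, and the libraries carried no length or GC trends. The rates may therefore not hold for the real comparison.

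In BR1, geldanamycin raised HSPA1A from 261 ± 6.36 CPM to 2736 ± 101 CPM, a log2 fold change of 3.39 ± 0.12 (adjusted p = 1.96e-15). CHAC1 rose from 4.03 ± 0.538 CPM to 24.4 ± 1.77 CPM (2.60 ± 0.17, adjusted p = 2.87e-10). DDIT4 (ENSG00000168209, chromosome 10, 72273919 to 72276036) rose from 53.7 ± 1.15 CPM to 253 ± 7.5 CPM. HSPB8 rose from 12.9 ± 1.41 CPM to 55.2 ± 1.71 CPM. HSPA1B (3.07 ± 0.13), SOCS1 (2.38 ± 0.13), DNAJB1 (2.14 ± 0.12) and the cytokine subunit gene EBI3 (2.04 ± 0.21) completed the largest rises. FOSB fell from 33.2 ± 1.07 CPM to 2.73 ± 1.36 CPM. The circadian repressor gene NR1D2 (-2.63 ± 0.15), PPFIA4 (-2.53 ± 0.16), MAFF (-2.26 ± 0.16), the insulin receptor substrate gene IRS2 (-2.12 ± 0.16), MYO3B (-2.04 ± 0.20), CREBRF (-2.03 ± 0.18) and KLF9 (-2.02 ± 0.12) completed the largest falls. PSMB5 rose from 207 ± 1.83 CPM to 338 ± 22.7 CPM (0.71 ± 0.10, adjusted p = 1.79e-05). SQSTM1 rose by 1.22 ± 0.12 and HSP90AA1 by 1.38 ± 0.12, and MCL1 did not pass (-0.06 ± 0.10, adjusted p = 0.685).

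Of 32 heat shock genes, 31 rose and 0 fell in treated BR1 cells, also when adjusted over the list alone (median 1.14, adjusted p = 4.62e-31, and adjusted p = 0.0326 with an estimated correlation). Of 33 proteasome genes, 30 rose and 0 fell (31 over the list alone, median 0.69, adjusted p = 1.04e-20), with ADRM1 at 1.23 ± 0.11 and PSMB4 at 0.94 ± 0.11. Of 29 glycolysis and hypoxia genes, 0 rose and 20 fell, also over the list alone (median -0.49, adjusted p = 7.52e-10). Of 23 ATF4 response genes, 13 rose and 1 fell (14 and 3 over the list alone, median 0.50, adjusted p = 0.00038). These 3 calls were lost with adjusted p = 0.0807 with an estimated correlation. Of 14 immediate early genes, 0 rose and 11 fell (12 over the list alone, median -0.97, adjusted p = 1.43e-07, lost with adjusted p = 0.279 with an estimated correlation). Of 53 ribosomal protein genes, 44 rose and 0 fell (46 over the list alone, median 0.51, adjusted p = 1.64e-16), with RPS21 at 1.01 ± 0.16. Of 40 oxidative phosphorylation genes, 28 rose and 2 fell, also over the list alone (median 0.53, adjusted p = 7.52e-10), with UQCRQ at 1.20 ± 0.14. Both calls were lost with adjusted p = 0.314 with an estimated correlation. Many ribosomal protein genes have processed pseudogenes that can share their reads. Log2 fold changes in BR1 fell with transcript length (rho = -0.417 across 8292 genes, against 0.00998 in wildtype cells and -0.0275 in BR2). Removal of each library's trends with length and GC content was incomplete here and left rho = -0.147 with length. After it, 39 ribosomal protein genes rose (median 0.34), 24 oxidative phosphorylation genes rose (median 0.39) and 30 proteasome genes rose (median 0.58). Of 13 mitochondrially encoded transcripts, 0 rose and 9 fell, also over the list alone (median -0.50, adjusted p = 0.00062, and adjusted p = 0.519 with an estimated correlation). This list did not pass without treated BR1 sample 2 (-0.23). Of 25 G2/M genes, 4 rose and 10 fell (5 and 10 over the list alone, median -0.15, adjusted p = 0.0277, and adjusted p = 0.447 with an estimated correlation), and they did not pass as a list without treated BR1 sample 1 (-0.15) or when fitted on their own 2 groups. In all, 6393 genes changed, 3185 higher and 3208 lower, and 1417 by at least 2-fold. The count was 3873 without BR1 sample 2, and 5627 of the 6393 genes were called in the same direction with length and GC trends removed.

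In BR2, geldanamycin raised HSPA1A from 222 ± 3.83 CPM to 3051 ± 38.4 CPM, a log2 fold change of 3.78 ± 0.12 (adjusted p = 2.55e-16). EBI3 rose from 5.91 ± 0.112 CPM to 31.6 ± 1.37 CPM, and CREB3L3 from 20.8 ± 0.68 CPM to 99.9 ± 16.3 CPM. HSPA1B (3.19 ± 0.13), SOCS1 (2.29 ± 0.13), HSPH1 (2.24 ± 0.12), DNAJB1 (2.08 ± 0.12) and PSPN (1.92 ± 0.23) completed the largest rises. FOSB fell from 25 ± 0.658 CPM to 2.23 ± 0.499 CPM. PPFIA4 (-2.62 ± 0.17), NR1D2 (-2.59 ± 0.16), DIPK1C (-2.56 ± 0.18), the Fc receptor gene FCGR2B (-2.45 ± 0.19), FOS (-2.40 ± 0.20), KLF10 (-2.33 ± 0.13) and MAFF (-2.30 ± 0.16) completed the largest falls. HSP90AA1 rose by 1.45 ± 0.12 and SQSTM1 by 0.91 ± 0.12, while PSMB5 (0.24 ± 0.10, adjusted p = 0.0841) and MCL1 (0.04 ± 0.10, adjusted p = 0.811) did not pass. Of 32 heat shock genes, 31 rose and 0 fell, also when adjusted over the list alone (median 1.06, adjusted p = 1.86e-29). Of 29 glycolysis and hypoxia genes, 0 rose and 22 fell (25 over the list alone, median -0.68, adjusted p = 8.87e-16). Both calls held with adjusted p = 0.038 and adjusted p = 0.0487 with an estimated correlation. Of 33 proteasome genes, 20 rose and 1 fell (26 and 2 over the list alone, median 0.36, adjusted p = 2.3e-09, lost with adjusted p = 0.218 with an estimated correlation). Of 22 cholesterol synthesis genes, 1 rose and 15 fell (1 and 16 over the list alone, median -0.47, adjusted p = 8.97e-07), with HMGCS1 falling from 612 ± 5.68 CPM to 342 ± 53.1 CPM. Of 14 immediate early genes, 0 rose and 12 fell, also over the list alone (median -1.28, adjusted p = 3.15e-10). Both were lost with adjusted p = 0.181 with an estimated correlation. Of 23 ATF4 response genes, 7 rose and 8 fell, also over the list alone (median -0.04, mean 0.07, adjusted p = 0.966). ATF5 stood at 1.02 ± 0.11, DDIT4 at 0.98 ± 0.11 and ATF3 at -1.27 ± 0.13. In all, 5997 genes changed, 2930 higher and 3067 lower, and 1753 by at least 2-fold. The count was 3795 without BR2 sample 1 and 3785 without BR2 sample 2.

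Much of the response was shared among the 3 lines. Geldanamycin changed 2683 genes in the same direction in wildtype, BR1 and BR2 cells. They were 1166 higher against 72.5 expected of independent lists and 1517 lower against 92.1 expected, while 145 genes rose in one line and fell in another. HSPA1A, HSPA1B, DNAJB1, HSP90AA1, SOCS1 and SQSTM1 rose and FOSB, MAFF and PPFIA4 fell in each line. The correlation of log2 fold changes across 8327 genes was 0.693 between wildtype cells and BR1, 0.811 between wildtype cells and BR2, and 0.778 between BR1 and BR2, although genes are not independent replicates.

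**Figure D2:**
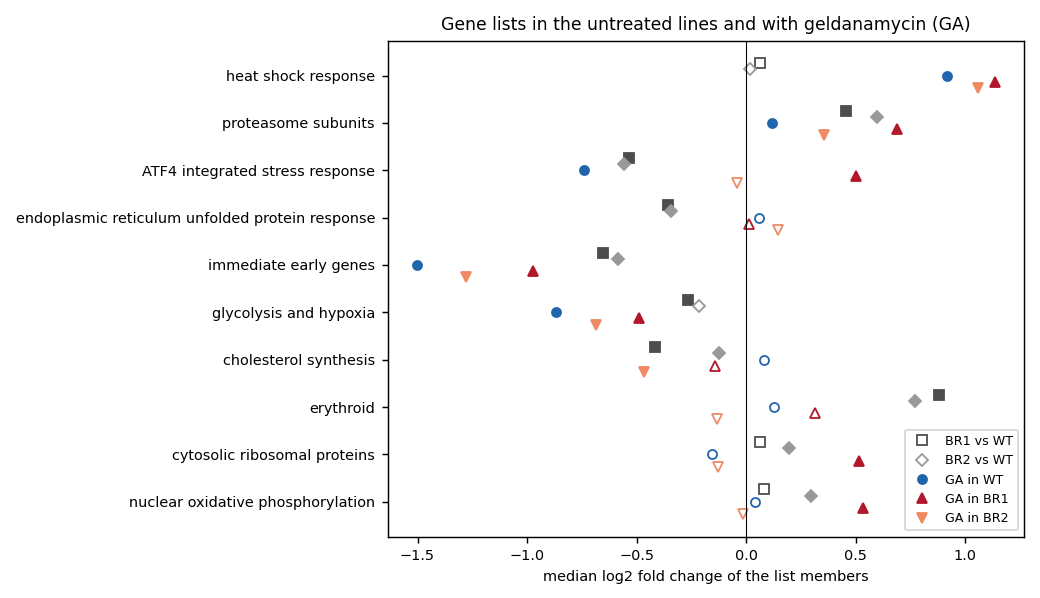
Median log2 fold change (horizontal axis) of 10 gene lists in BR1 and BR2 against wildtype cells (square and diamond) and with geldanamycin in wildtype, BR1 and BR2 cells (circle, upward and downward triangle), filled where camera with its preset correlation gave an adjusted p under 0.05. The heat shock list stands at 0.91, 1.14 and 1.06 with geldanamycin, and the ATF4 list at -0.74, 0.50 and -0.04.

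The difference between the responses of each resistant line and wildtype cells was tested by itself. CHAC1 fell from 21.6 ± 1.37 CPM to 5.43 ± 1.15 CPM in wildtype cells while it rose in BR1, a difference of log2 responses of 4.56 ± 0.25 (adjusted p = 4.36e-11). DDIT4 stood at 131 ± 7.13 and 94.5 ± 6.73 CPM in untreated and treated wildtype cells, a difference of 2.70 ± 0.16 (adjusted p = 1.2e-10). Responses in BR1 also exceeded those in wildtype cells for ADM2 (2.40 ± 0.31), FAM241B (2.35 ± 0.26), ATF3 (2.20 ± 0.19), PDGFA (2.12 ± 0.23), SLC7A11 (1.86 ± 0.21) and NR4A1 (1.72 ± 0.35). Responses were lower in BR1 for CAMK1D (-3.35 ± 0.61), CREB3L3 (-3.20 ± 0.26), VGF (-1.87 ± 0.32), QRICH2 (-1.77 ± 0.26), CA12 (-1.72 ± 0.25), A2ML1 (-1.69 ± 0.28), NCR3LG1 (-1.64 ± 0.33) and PLB1 (-1.59 ± 0.28). CAMK1D had very few counts in untreated wildtype cells, so the size of its difference is uncertain. Of 23 ATF4 genes, 19 responded more and 0 less in BR1 (20 and 0 over the list alone, median difference 1.22, adjusted p = 3.98e-34, and adjusted p = 0.000562 with an estimated correlation). Of 10 growth arrest genes, 5 responded more and 0 less (8 and 1 over the list alone, median 0.75, adjusted p = 1.39e-06, and adjusted p = 0.0249 with an estimated correlation), with GADD45B at 1.42 ± 0.20. Of 33 proteasome genes, 18 responded more and 0 less (31 and 0 over the list alone, median 0.57, adjusted p = 9.7e-20, lost with adjusted p = 0.0733 with an estimated correlation), with PSMD14, a deubiquitinase of the proteasome lid, at 0.74 ± 0.15. Of 53 ribosomal protein genes, 40 responded more and 0 less (51 and 0 over the list alone, median 0.67, adjusted p = 3.24e-34, lost with adjusted p = 0.206 with an estimated correlation). Of 40 oxidative phosphorylation genes, 14 responded more and 0 less (22 and 0 over the list alone, median 0.50, adjusted p = 1.96e-10, lost with adjusted p = 0.327 with an estimated correlation). This difference fell with transcript length (rho = -0.542 across 8292 genes), from a median of 0.706 for the 80 genes with transcripts up to 600 nucleotides to -0.16 for the 3039 genes over 4000 nucleotides. Removal of each library's trends with length and GC content left rho = -0.13 with length, so these medians may still hold part of the trend. They were then 0.45, 0.46 and 0.31 for the proteasome, ribosomal protein and oxidative phosphorylation lists. Of their genes, 18, 18 and 6 responded more in BR1.

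The BR1 and wildtype responses differed at 1098 genes, 679 more positive and 419 more negative in BR1, and 3768 genes had an unadjusted p under 0.05. With length and GC trends removed, 1022 genes were called, and 688 of the 1098 were among them in the same direction. That count depended on single libraries and was 643 without wildtype sample 1, 667 without wildtype sample 2, 304 without BR1 sample 1, 208 without BR1 sample 2, 232 without treated wildtype sample 1, 1773 without treated BR1 sample 1 and 427 without treated BR1 sample 2. PSMB5 responded more in BR1 (0.66 ± 0.15, adjusted p = 0.0132), a call that did not pass without BR1 sample 1 (0.67) or 2 (0.63) or treated wildtype sample 1 (0.59).

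**Figure D3:**
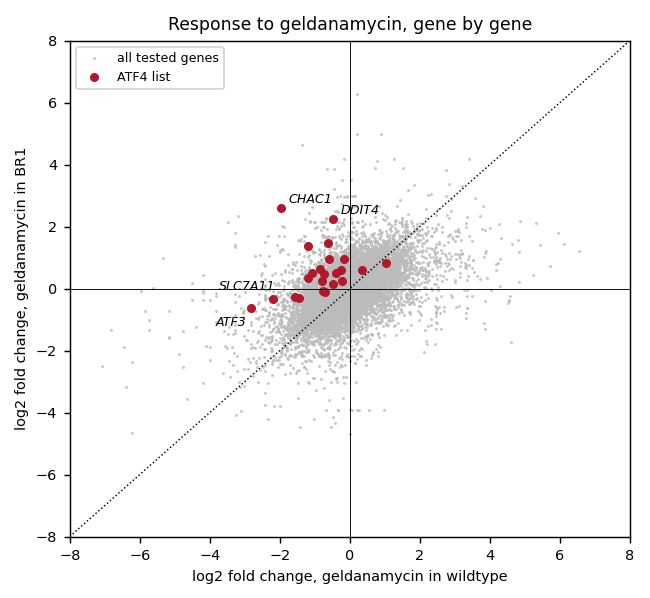
Log2 fold change with geldanamycin in wildtype cells (horizontal axis) against that in BR1 (vertical axis), where each grey point is 1 of 18490 genes tested, red points are the 23 ATF4 list genes and the dotted line marks equal responses. CHAC1, DDIT4, ATF3 and SLC7A11 lie above the line, by 4.56, 2.70, 2.20 and 1.86.

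BR2 and wildtype responses differed at fewer genes, 208 in all, 117 more positive and 91 more negative in BR2, with 2334 at an unadjusted p under 0.05. The count was 322 without a count filter, 352 with DESeq2 and 581 with length and GC trends removed. CHAC1 rose from 2.73 ± 0.302 CPM to 7.23 ± 0.408 CPM in BR2, a difference of 3.37 ± 0.27 from wildtype cells (adjusted p = 1.71e-07). Responses also exceeded those in wildtype cells for SLC7A11 (2.12 ± 0.22), PDGFA (2.07 ± 0.23), the oxidative stress gene OSGIN1 (1.66 ± 0.18), PHLDA1 (1.64 ± 0.26) and FAM241B (1.64 ± 0.25). They were lower for CREB3L3 (-2.37 ± 0.27), PLB1 (-1.84 ± 0.28), CD84 (-1.68 ± 0.27), the Notch target HES1 (-1.53 ± 0.19), CA12 (-1.53 ± 0.25) and ID2 (-1.47 ± 0.19). The calls for NR4A1, A2ML1 and NCR3LG1 depended on single libraries. NR4A1 (1.92 ± 0.37) did not pass without BR2 sample 2 (1.86) or treated wildtype sample 2 (1.92), and A2ML1 (-1.70 ± 0.29) did not pass without BR2 sample 1 (-1.46). NCR3LG1 (-1.48 ± 0.34) did not pass without wildtype sample 2 (-1.11), BR2 sample 1 (-1.36) or 2 (-1.59), treated wildtype sample 2 (-1.29) or treated BR2 sample 1 (-1.03), nor with DESeq2, with the stricter count filter or when fitted on the compared groups only. Of 23 ATF4 genes, 10 responded more and 0 less in BR2 (18 and 0 over the list alone, median 0.71, adjusted p = 1.33e-23, and adjusted p = 0.00171 with an estimated correlation). Of 22 cholesterol synthesis genes, 0 responded more and 6 less (14 over the list alone, median -0.47, adjusted p = 6.41e-17, and adjusted p = 0.0233 with an estimated correlation). Of 24 erythroid genes, 0 responded more and 1 less (9 over the list alone, median -0.38, adjusted p = 4.4e-07, and adjusted p = 0.0153 with an estimated correlation). The gene count was 111 without wildtype sample 2, 48 without BR2 sample 1, 60 without BR2 sample 2, 124 without treated wildtype sample 1, 80 without treated wildtype sample 2 and 443 without treated BR2 sample 2. Whether the responses of BR1 and BR2 differed was tested too, and 270 genes did, 45 more positive and 225 more negative in BR2. This difference rose with transcript length (rho = 0.583 across 8292 genes).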

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

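The tests of transcript length and GC content and of the level in untreated wildtype cells were chosen only after the result was seen, while the tests that leave out 1 library were chosen before. Every result in this part was singled out because the response to geldanamycin differed between cell lines in edgeR's test of the difference itself or, for lists, in camera's test of it.

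Responses of BR1 and wildtype cells differed at 1098 genes, of which 688 were called in the same direction with length and GC trends removed, and the count ranged from 208 without BR1 sample 2 to 1773 without treated BR1 sample 1. It was 643 without wildtype sample 1, 667 without wildtype sample 2, 304 without BR1 sample 1, 232 without treated wildtype sample 1 and 427 without treated BR1 sample 2. Responses of BR2 and wildtype cells differed at 208 genes, and the count ranged from 48 without BR2 sample 1 to 443 without treated BR2 sample 2. It was 111 without wildtype sample 2, 60 without BR2 sample 2, 124 without treated wildtype sample 1 and 80 without treated wildtype sample 2. With other settings it was 322 without a count filter, 352 with DESeq2 and 581 with length and GC trends removed. Responses of BR2 and BR1 differed at 270 genes, for which single libraries were not left out.

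Among the 8 largest differences in each direction and the 17 genes followed in every comparison, those more positive in BR1 than in wildtype cells were CHAC1 (difference of log2 responses 4.56), DDIT4 (2.70), ADM2 (2.40), FAM241B (2.35), ATF3 (2.20), PDGFA (2.12), SLC7A11 (1.86), NR4A1 (1.72), HSPA1B (0.73), DNAJB1 (0.72), HBG1 (0.70), MCL1 (0.67), PSMB5 (0.66) and HSPA1A (0.55). Those more negative in BR1 were CAMK1D (-3.35), CREB3L3 (-3.20), VGF (-1.87), QRICH2 (-1.77), CA12 (-1.72), A2ML1 (-1.69), NCR3LG1 (-1.64) and PLB1 (-1.59). The CAMK1D difference rests on very few counts in untreated wildtype cells. For MCL1 the change was mainly in wildtype cells, from 511 to 308 CPM, against 281 and 270 CPM in untreated and treated BR1. Without BR1 sample 1, BR1 sample 2 or treated wildtype sample 1, the calls for MCL1 (0.62, 0.69 and 0.67), PSMB5 (0.67, 0.63 and 0.59) and HSPA1B (0.68, 0.77 and 0.73) did not pass, and DNAJB1 did not pass without BR1 sample 2 (0.68) or treated wildtype sample 1 (0.67). HSPA1A did not pass without wildtype sample 1 (0.54) or 2 (0.55), BR1 sample 1 (0.57) or 2 (0.50), or treated wildtype sample 1 (0.64) or 2 (0.46). HBG1 did not pass without wildtype sample 1 (0.67) or 2 (0.74), BR1 sample 1 (0.70) or 2 (0.68), treated wildtype sample 1 (0.57) or treated BR1 sample 2 (0.42), nor with length and GC trends removed (0.39).

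Among the same kinds of genes, those reported here as more positive in BR2 than in wildtype cells were CHAC1 (3.37), SLC7A11 (2.12), PDGFA (2.07), NR4A1 (1.92), OSGIN1 (1.66), PHLDA1 (1.64), FAM241B (1.64), HSPA1A (0.93), HSPA1B (0.86), MCL1 (0.77) and DNAJB1 (0.67). Those more negative in BR2 were CREB3L3 (-2.37), PLB1 (-1.84), A2ML1 (-1.70), CD84 (-1.68), HES1 (-1.53), CA12 (-1.53), NCR3LG1 (-1.48) and ID2 (-1.47). MCL1 stood at 247 and 254 CPM in untreated and treated BR2, so its difference again lay mainly in the fall in wildtype cells. HSPA1B and MCL1 did not pass without BR2 sample 1 (0.82 and 0.78) or 2 (0.90 and 0.75) or treated wildtype sample 2 (0.86 and 0.76). NR4A1 did not pass without BR2 sample 2 (1.86) or treated wildtype sample 2 (1.92), and A2ML1 without BR2 sample 1 (-1.46). NCR3LG1 did not pass without wildtype sample 2 (-1.11), BR2 sample 1 (-1.36) or 2 (-1.59), treated wildtype sample 2 (-1.29) or treated BR2 sample 1 (-1.03), nor with DESeq2, the stricter filter or a fit on the compared groups only. DNAJB1 did not pass without wildtype sample 1 (0.67) or 2 (0.67), BR2 sample 1 (0.62) or 2 (0.72), treated wildtype sample 1 (0.61) or 2 (0.73), or treated BR2 sample 2 (0.51).

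Lists whose median response was higher in BR1 than in wildtype cells were the ATF4 response (1.22), growth arrest (0.75), cytosolic ribosomal proteins (0.67), immediate early genes (0.63), proteasome subunits (0.57), nuclear oxidative phosphorylation (0.50), autophagy and ubiquitin receptors (0.28), glycolysis and hypoxia (0.27) and the heat shock response (0.22). Mitochondrially encoded transcripts (-0.31) and cholesterol synthesis (-0.10) had more negative responses in BR1. With an estimated correlation only the ATF4 and growth arrest lists still passed. The immediate early, autophagy and glycolysis lists did not pass without treated BR1 sample 1 (0.29, 0.32 and 0.23), the heat shock list without wildtype sample 2 (0.15), and the cholesterol list without treated wildtype sample 2 (-0.09). The mitochondrially encoded list did not pass without wildtype sample 1 (-0.25), treated wildtype sample 1 (-0.11) or treated BR1 sample 2 (-0.07), nor with the stricter filter. Immediate early and glycolysis genes stood lower in untreated BR1 than in untreated wildtype cells (medians -0.65 and -0.26). Between treated BR1 and treated wildtype cells neither list passed camera's test (-0.07 and -0.03, adjusted p = 0.531 and 0.964). Their response differences thus go with different untreated levels, not with a higher level in treated BR1.

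Lists whose median response was higher in BR2 than in wildtype cells were the ATF4 response (0.71), mitochondrially encoded transcripts (0.42), growth arrest (0.25), NRF2 targets (0.24), proteasome subunits (0.23), the heat shock response (0.17) and autophagy and ubiquitin receptors (0.15). Cholesterol synthesis (-0.47), erythroid genes (-0.38) and epithelial markers (-0.23) had more negative responses in BR2. With an estimated correlation only the ATF4, erythroid and cholesterol lists still passed. The NRF2 list did not pass without wildtype sample 2 (0.16) or treated BR2 sample 2 (0.25), the heat shock list without treated BR2 sample 2 (0.07), and the mitochondrially encoded list without treated BR2 sample 1 (0.21). The autophagy list did not pass without wildtype sample 2 (0.12), treated wildtype sample 1 (0.11) or treated BR2 sample 2 (0.01), and the epithelial list without wildtype sample 1 (-0.23), BR2 sample 2 (-0.17), treated wildtype sample 1 (-0.22) or treated BR2 sample 2 (-0.28). Without a count filter the NRF2 and epithelial lists did not pass, and with the stricter filter the epithelial list did not pass.

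With geldanamycin 17 of 23 ATF4 response genes fell and 1 rose in wildtype cells (median -0.74) and in BR1 13 of 23 rose and 1 fell (0.50, lost with adjusted p = 0.0807 with an estimated correlation), and the list did not pass in BR2 (-0.04). A trend with transcript length or GC content is argued against for BR1, since the median difference of 1.22 stood at the 99.99th percentile of 10000 random lists matched on length, GC content and expression, the highest they can give, with a random median of 0.087. A single library is argued against too, because the median was at least 1.15 whichever of the 8 libraries was left out, and a high level in untreated wildtype cells alone would not leave treated BR1 above treated wildtype cells by a median of 0.708 (adjusted p = 0.0207 with an estimated correlation). For BR2 the same median was 0.379 (adjusted p = 0.218 with an estimated correlation), so a lasting difference and a higher starting level in wildtype cells cannot be told apart with 2 samples per group. A difference between the lines in the ATF4 response to HSP90 inhibition may remain for BR1 as a hypothesis found and tested on the same data.

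Ribosomal protein, oxidative phosphorylation and proteasome genes responded more in BR1 than in wildtype cells, in a comparison where shorter transcripts also responded more (rho = -0.542), and both untreated and treated BR1 libraries carried the trend, with rho against the mean of all libraries of 0.299 and 0.333 untreated, -0.243 and -0.396 treated, and -0.122 to 0.139 in the other libraries. Random lists matched on length, GC content and expression had medians of 0.294, 0.271 and 0.199. A length or GC trend may therefore account for part of the medians of 0.67, 0.50 and 0.57. These stood at the 99.99th, 99.98th and 99.99th percentiles of such lists, which argues against that trend as the whole source for proteasome genes. The matching used annotated transcript lengths, which may exceed those of the transcripts present. Genes outside the ribosomal list with transcripts up to 600 and of 600 to 1000 nucleotides had medians of 0.706 and 0.533. For ribosomal protein and oxidative phosphorylation genes the percentiles therefore cannot exclude the length trend as the whole source. A single library is argued against by the lowest of the 3 medians with 1 library left out, 0.289 for oxidative phosphorylation without treated BR1 sample 2, although that library carried part of the size, with 0.472 for ribosomal proteins and 0.463 for proteasome genes without it. All 3 calls were lost in camera with an estimated correlation (adjusted p = 0.206, 0.327 and 0.0733). For geldanamycin in BR1 the correlation estimated from the residuals was 0.525, 0.288 and 0.196 for these lists, so their members moved together within groups as well. RNA quality was not given in the sources used here, ribosomal protein genes held 10.6% and 12.8% of counts in treated BR1 libraries against 7.79% to 9.91% in the others, and a biological difference between the lines remains an untested explanation.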

How the results depend on the processing

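Removal of each library's trend with transcript length and GC content and the block with crossed sample numbers were chosen only after the result was seen, and the other settings were planned before the data were examined. No named gene and no list that passed, either as reported or under the setting tried, changed its sign under any setting that was run. List medians that passed in neither case could change sign, as for mitochondrially encoded transcripts in BR2 against BR1 (from 0.035 to -0.084 with the length and GC trend removed). With RLE size factors 1037 of 1043 results for named genes kept their side of the threshold, with DESeq2 969 of 1010, and with the authors' deposited values 421 of 441. The numbers were, without a count filter 1002 of 1043, with the stricter filter 911 of 930, with only the groups compared 966 of 1026, and with both lines pooled 115 of 119. The count of response differences between BR2 and wildtype cells moved from 208 to 322 without a filter, 352 with DESeq2 and 581 with the length and GC trend removed. BR2 against BR1 gave 4636 genes in place of 1649 when fitted on its own 2 groups. The cause of these 4 moves was not tested. The spread was unequal, with a common coefficient of variation between samples of 4.43% in BR1 and 4.47% in BR2. It was 10.1% in wildtype cells and 8.13%, 12.2% and 13.3% in treated wildtype, BR1 and BR2 cells. The main test shares the spread over all groups, while the fit of BR2 against BR1 alone uses only that of the 2 least variable groups. With the length and GC trend removed, the share of higher genes among those called went from 48.0% to 52.0% for BR2 against BR1, from 48.6% to 50.3% for BR2 against wildtype cells and from 49.8% to 51.4% for geldanamycin in BR1. Then 994 of 1043 gene results and 253 of 270 list results kept their side, and 16 and 13 calls were lost.

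A requirement of adjusted p under 0.05 and at least 2-fold, which by construction passes fewer genes, gave 2592 genes for the resistant lines against wildtype cells, 2614 for BR1, 2481 for BR2, 695 for BR2 against BR1, 1580, 1417 and 1753 for geldanamycin in wildtype, BR1 and BR2 cells, 273 and 72 for the response differences of BR1 and BR2, and 392 genes shared by all 3 responses. Adjusted p under 0.01 gave 964 for BR2 against BR1, 3733, 4213 and 3869 for geldanamycin in wildtype, BR1 and BR2 cells, 227 and 75 for the response differences and 1606 shared genes. Of 97 list calls over the 9 comparisons, 18 held with an estimated correlation, and fry kept the side of 197 of 270 list results.

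With 1 library left out, the lone sample of its group is assumed to vary like the other groups. BR2 against BR1 then gave 748 (without BR2 sample 2) to 887 genes (without BR2 sample 1), with 848 and 846 without BR1 sample 1 and 2. Geldanamycin in BR1 gave 3873 (without BR1 sample 2) to 5528, and in BR2 3785 (without BR2 sample 2) to 5708, with 3795 without BR2 sample 1. Response differences numbered 208 (without BR1 sample 2) to 1773 (without treated BR1 sample 1) for BR1, with 643 and 667 without wildtype sample 1 and 2, 304 without BR1 sample 1, 232 without treated wildtype sample 1 and 427 without treated BR1 sample 2. For BR2 they numbered 48 (without BR2 sample 1) to 443 (without treated BR2 sample 2), with 60 without BR2 sample 2, 111 without wildtype sample 2, and 124 and 80 without treated wildtype sample 1 and 2. The other counts stayed within 1.5 times, at 4835 to 5851 for the resistant lines, 4301 to 5055 for BR1, 3927 to 4745 for BR2, 3996 to 4379 for geldanamycin in wildtype cells and 1944 to 2574 shared genes.

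With the sample number as a replicate block, the counts were 6788 for the resistant lines, 6301 for BR1, 5873 for BR2, 1718 for BR2 against BR1, 6003, 6501 and 6151 for geldanamycin in wildtype, BR1 and BR2 cells, 1237 and 230 for the response differences and 2741 shared genes, with 98 list calls. Within wildtype cells alone, a block of crossed sample numbers called 7495 genes and a block of equal numbers 5090. Each technical replicate as its own sample, and the first technical replicate alone, were not run, since the tables hold 1 column per sample, and other pseudocounts were not run, since counts were tested. With 2 samples per group and 10347281 to 22799884 counts, calls that missed the threshold do not show that levels were equal.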

Other observations

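The comparisons of treated lines and the tests of transcript length, GC content and copy number were chosen only after the result was seen, while the test on treated libraries of the chromosome 17 pattern was chosen before.

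Treated resistant cells were also compared with treated wildtype cells. Of 33 proteasome subunit genes, 32 were higher and 0 lower in treated BR1 (median 1.09, adjusted p = 7.61e-28, and adjusted p = 0.0305 with an estimated correlation) and likewise 32 and 0 in treated BR2 (median 0.87, adjusted p = 5.63e-24, lost with adjusted p = 0.0678 with an estimated correlation). PSMB5 stood at 174 ± 12.5 CPM (SD, n = 2) in treated wildtype cells, 338 ± 22.7 CPM in treated BR1 and 291 ± 23.3 CPM in treated BR2. Of 24 erythroid genes, 15 were higher and 2 lower in treated BR1 (median 0.84, adjusted p = 4.06e-07, and adjusted p = 0.0207 with an estimated correlation), and 11 were higher and 2 lower in treated BR2 (median 0.47, adjusted p = 0.00132, lost with adjusted p = 0.0678 with an estimated correlation). Of 22 cholesterol synthesis genes, 0 were higher and 14 lower in treated BR1 (median -0.41, adjusted p = 1.66e-08) and 0 and 18 in treated BR2 (median -0.61, adjusted p = 8.73e-13), both lost with adjusted p = 0.0986 and adjusted p = 0.0678 with an estimated correlation. Log2 fold changes of treated BR1 against treated wildtype cells fell with transcript length (rho = -0.297 across 8292 genes, and -0.103 for BR2). With each library's trends with length and GC content removed, the proteasome, erythroid and cholesterol medians were 0.96, 0.71 and -0.35 in treated BR1 and 0.81, 0.43 and -0.62 in treated BR2. These comparisons called 6654 genes for BR1 and 5333 for BR2, and single libraries were not left out.

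Genes along part of chromosome 17 were lower in both resistant lines. The 344 tested genes that start from position 30000001 on (GRCh38) had a median log2 fold change of -0.473 in BR1 and -0.5 in BR2, against 0.0318 and 0.0326 for genes on other chromosomes, and 246 of them were called lower and 16 higher in the resistant lines. A trend with transcript length or GC content is argued against, since the median over both lines was -0.494 with that trend removed, and a chance deviation of the untreated wildtype libraries is argued against by medians of -0.42 and -0.508 between treated libraries, which share no library with the untreated comparison. At least 83.1% of the genes were below 0 in each of the 4 comparisons, as a lower copy number of the region in both lines would give. That criterion was set after the values were seen, so the share restates the pattern and is no separate support. A lower copy number remains a hypothesis found in these data. No DNA was measured, and lower transcription over the region would give the same values. Genes named above that lie in the region, such as NFE2L1 and ERN1, fell along with their neighbours. Their falls may therefore be partly or wholly this regional shift.

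Among 147 windows of 10 Mb with at least 20 genes, the 5 lowest medians in BR1 and the 7 lowest in BR2 lay on chromosome 17. Its windows from 1 to 10000000 and from 10000001 to 20000000 were not lower, at 0.031 and 0.145 in BR1 and -0.019 and 0.116 in BR2. The medians of the lines differed near the start of the region, where the window from 20000001 to 30000000, which lies outside it, stood at -0.063 in BR1 and -0.377 in BR2. The first window inside it, from 30000001 to 40000000, stood at -0.27 in BR1 and -0.42 in BR2. In that window 69.1% and 89.1% of 55 genes were below 0. The difference between the lines was not tested by window. In BR2 the window of chromosome 16 from 60000001 to 70000000 stood at 0.53 (49 genes, 0.10 in BR1), and in BR1 the window of chromosome 22 from 10000001 to 20000000 stood at -0.38 (25 genes, -0.14 in BR2).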
